A study of Rattus norvegicus with 38 samples.

How the data were processed

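Lung RNA of 38 animals was measured on Affymetrix Rat Genome 230 2.0 arrays, 1 array per animal. Per the labels' protocols, total RNA was extracted from about 25 mg of lung with an RNeasy kit, checked on an Agilent 2100 bioanalyzer and labelled with biotin. The labels describe separate animals, and groups were taken from them. Array numbers run in blocks by group, so the order of the numbers and the group cannot be told apart. No scan date was used here.

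The table deposited by the authors holds linear intensity values, from 2.09 to 11560, for 31099 probe sets. The software that summarised and normalized the intensities is not given in the sources used here. The values were analysed as log2(intensity + 16) with no further normalization. Of the probe sets, 57 were controls, 20826 had 1 gene symbol, 436 had several and 9780 had none in the platform annotation. A gene ID in the RefSeq gene table was found for 20758 of the 20826, and 0 symbols were updated. For each gene the probe set with 1 symbol and the highest mean over all arrays was used, which gave 14217 genes, 4525 of them with more than 1 probe set.

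Differential expression was tested with limma 3.58.1 (lmFit and eBayes, moderated and two-sided) in R 4.3.3. The 4 group means were fitted over all 38 arrays, with 34 residual degrees of freedom (36.22 with the prior). The 5 contrasts cover smoke in each line, the line difference under each exposure, and the interaction, which is the smoke change in LCR minus that in HCR. P-values were adjusted by Benjamini-Hochberg over the 14217 genes, with a threshold of 0.05. Each adjusted p of a gene is from limma.

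Gene lists were written from textbook knowledge and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Of 42 lists, 41 were tested, because thymus markers had 2 measured members and 5 were required. The estimated correlation and fry, which tests whether the members move 1 way on balance without comparing them with other genes, were alternatives. Members were also counted with p adjusted over the list alone.

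Named genes were the 10 largest changes per direction among genes that passed, up to 3 passing members of each list by p, and 9 fixed sentinel genes. Cxcl9, Cd163, Il33, Muc5b, Agr2, Gp2, Bmal1, Clock, Per1, Bhlhe40, Eln, Hbb and Jchain fall outside this rule and were chosen after their values were seen. The comparisons, lists, naming rule and the alternatives listed last, except where said otherwise, were chosen before the data were examined.

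Array quality measures were compared by exact permutation tests, or 100000 resamples between groups of 12, in SciPy 1.17.1 with NumPy 2.4.6, pandas 2.3.3 and Python 3.11.15. These tests were two-sided, 20 in number, and adjusted together. Correlations of changes between comparisons were set against 100 draws of permuted labels, the real labels included. Figures were drawn with matplotlib 3.10.9. Array correlations lay between 0.962 and 0.997, and at most 0.0612% of probe sets held identical values in 2 arrays.

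On simulated data with known changes, the test recovered 95.5% of genes changed by 0.5 log2 in HCR, 97.0% in LCR, 88.1% between lines under sham, 94.0% under smoke and 86.6% in the interaction. False calls made up 3.45%, 3.92%, 7.73%, 3.45% and 6.47% of the calls. The simulated noise was normal, independent between genes and equal on all arrays, so these rates need not hold for the real arrays.

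Alternatives were quantile normalization, median-centred arrays, a filter on low genes, the mean of a gene's probe sets, all probe sets, a pseudocount of 1, only the groups compared in the fit, an intensity trend with robust variance, array weights, the Gapdh 3' minus 5' difference as a covariate, a size minimum, and each array left out. The interquartile range and the Actb difference as covariates, and the list tests without HCR sham 0432, HCR sham 0433 or LCR sham 0442 and without HCR smoke 0410, 0414, 0415 and 0417, singly and together, were chosen after seeing the data.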

Results

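Lung expression was measured in 38 female rats, 34 weeks old, from 2 lines selectively bred for high (HCR) or low (LCR) intrinsic running capacity. Animals breathed cigarette smoke or room air (sham) on 5 days per week, and lungs were taken after 12 weeks. The 4 groups held 7 HCR sham, 12 HCR smoke, 7 LCR sham and 12 LCR smoke animals, each with RNA from about 25 mg of lung on its own Affymetrix array. The design asks what smoke changed in each line, how the lines differed under either exposure, and whether the lines responded differently. Changes are differences of log2(intensity + 16) with their standard error, a scale that understates the change of low genes. The number of arrays limits the precision. Array numbers run in blocks by group, so an effect of their order cannot be told apart from smoke or line.

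The first principal component, with 34.9% of the variance, separated every smoke array from every sham array. The second, with 16.1%, spread arrays within groups. LCR sham 0442 had the highest heart muscle list mean of its group, at 3.31 log2 above the mean of all arrays, against -0.71 to 0.43 on the other LCR sham arrays. HCR sham 0433 had a skeletal muscle list mean of 3.77 (-0.15 to -0.03 on the other HCR sham arrays) and a fat cell list mean of 2.37 (-0.26 to 0.42), with a heart muscle list mean of 2.09. HCR smoke 0415, 0410, 0414 and 0417 had heart muscle list means of 3.08, 2.51, 1.51 and 1.17, against -0.68 to 0.41 on the other HCR smoke arrays. The interquartile range of log2 values was narrower on smoke than on sham arrays, at 2.86 ± 0.06 (SD, n = 12) against 2.99 ± 0.04 (SD, n = 7) in HCR (exact permutation p = 4.0e-05) and 2.91 ± 0.08 against 2.999 ± 0.02 in LCR (exact permutation p = 0.00254). The array median was lower on smoke arrays too, at 5.965 ± 0.024 against 6.009 ± 0.027 log2 in HCR (exact permutation test, adjusted p = 0.00699). In LCR it was 5.976 ± 0.030 against 6.034 ± 0.019 (exact permutation test, adjusted p = 0.000794). The 3' minus 5' log2 difference of the Actb control probe sets, a sign of RNA degradation, was lower on smoke arrays in LCR (0.65 ± 0.04 against 0.84 ± 0.14, exact permutation p = 0.000516, adjusted p = 0.00258) and did not pass after adjustment in HCR (0.67 ± 0.07 against 0.93 ± 0.51, adjusted p = 0.0642). That of Gapdh was lower on smoke arrays in LCR too (exact permutation test, adjusted p = 0.0155). The mean correlation of an array with its group was lower in HCR than in LCR under sham (0.9851 against 0.9916, exact permutation test, adjusted p = 0.0133). Under smoke it was 0.9898 against 0.9931 (permutation test, adjusted p = 0.000397), and HCR sham lay below HCR smoke (exact permutation test, adjusted p = 0.0236). The mean correlations of a group share pairs of arrays and were not recomputed for permuted groups. The p-values of this measure therefore cannot decide whether the groups differ in spread.

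**Figure D1:**
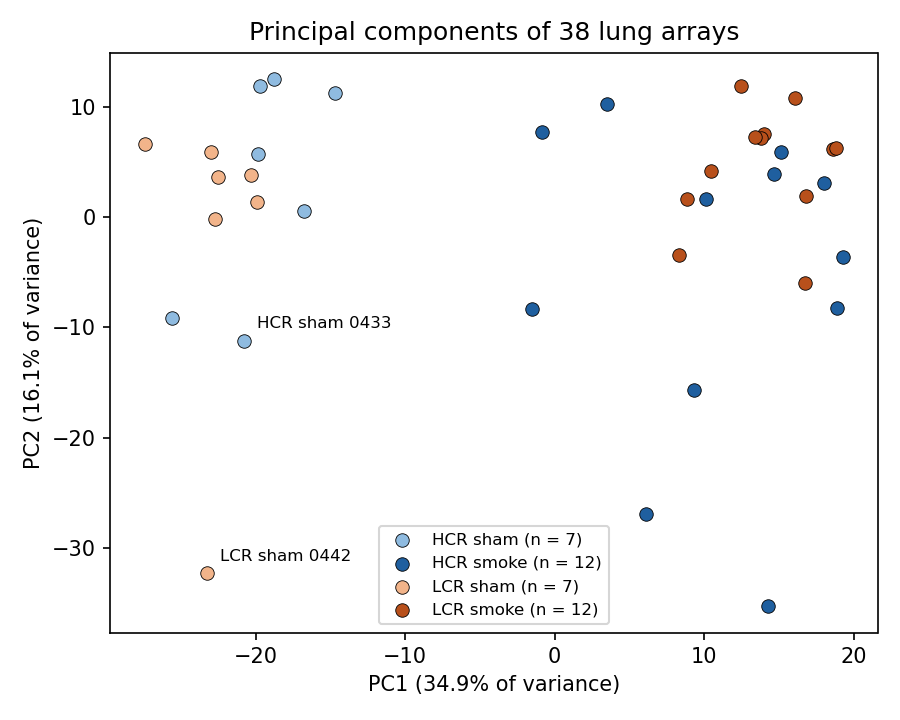
Each point is 1 array placed by its first (x axis, 34.9% of variance) and second (y axis, 16.1% of variance) principal component scores over 14217 genes, coloured by group. Sham and smoke arrays lie apart along the first component, and LCR sham 0442 lies lowest of the sham arrays on the second.

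In HCR animals, the largest rises with smoke were in Cyp1a1 and Aldh3a1. Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, rose by 7.19 ± 0.14 log2 (SE, adjusted p = 2.3e-31), from an intensity of 8.717 ± 3.603 (SD, n = 7) to 3607 ± 522 (SD, n = 12). Aldh3a1, an aldehyde dehydrogenase, rose by 3.82 ± 0.24 and Cyp1b1, another P450 of the same receptor, by 2.80 ± 0.25. Mmp12, the macrophage elastase, rose by 3.17 ± 0.39 and Lpo, the airway lactoperoxidase, by 3.41 ± 0.40. Each of these 5 genes was above the sham mean on 12 of 12 smoke arrays. Cxcl6 (2.88 ± 0.31), Ccl2 (2.52 ± 0.29), Orm1 (2.59 ± 0.37), Slc26a4 (2.37 ± 0.25) and Bpifb1 (2.37 ± 0.45) completed the 10 largest rises. The 10 largest falls were Mlc1 (-1.82 ± 0.22), Dlk1 (-1.69 ± 0.29), the B cell scaffold gene Bank1 (-1.42 ± 0.15), Slc6a15 (-1.37), Spon2 (-1.31), Tent5b (-1.31), Nxpe1 (-1.27), Syndig1 (-1.27), Siglec5 (-1.23) and Slc15a2 (-1.21). With the interquartile range as a covariate the call of Slc6a15 ended (adjusted p = 0.15).

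Of the 14217 genes, 6830 passed an adjusted p of 0.05 in HCR, 2513 higher and 4317 lower after smoke. Most changes were small, with a median size of 0.23 log2 among the genes called. At least 1.5-fold changes were called for 453 genes (225 higher, 228 lower), and at least 2-fold changes for 94 (70 higher, 24 lower). Higher calls made up 36.8%, between 26.2% with the lowest genes left out and 53.1% with median-centred arrays. Array medians were lower on smoke arrays, so the direction of small changes depends on centring. With the interquartile range of each array as a covariate, chosen after seeing the data, the count fell to 3023. This range differed between smoke and sham arrays. As a covariate it can therefore also remove part of the smoke change itself, here and in the other smoke results.

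Xenobiotic and antioxidant genes rose together in HCR. Of 8 measured aryl hydrocarbon receptor targets, 6 rose (6 adjusted over the list alone), with a median of 2.02 (set test adjusted p = 1.6e-10; adjusted p = 0.000418 with an estimated correlation). Of 35 NRF2 and glutathione genes, which protect against oxidants, 23 rose and 2 fell (23 and 2 adjusted over the list alone), including Nqo1 (2.34 ± 0.12), Hmox1 (1.72 ± 0.28), Gclc (1.27 ± 0.17) and Txnrd1 (1.10 ± 0.14). The call of the NRF2 list (adjusted p = 7.5e-10) was lost at adjusted p = 0.288 with an estimated correlation.

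Inflammatory groups rose as well in HCR. Of 30 cytokine and chemokine genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone; adjusted p = 2.3e-11, and adjusted p = 0.0364 with an estimated correlation). They included the neutrophil attractants Cxcl1 (1.94 ± 0.16) and Cxcl2 (2.30 ± 0.24), and Cxcl9 was among those that fell (-0.57). Neutrophil markers rose in 6 of 10 genes (6 adjusted over the list alone), among them S100a8 (1.81 ± 0.35), S100a9 (2.29 ± 0.28) and Lcn2 (2.09 ± 0.43), and this list had adjusted p = 0.464 with an estimated correlation. Macrophage markers rose in 11 and fell in 4 of 20 genes (12 and 4 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), with C1qb (1.06 ± 0.12) higher and Cd163 lower (-0.77). Lysosomal genes rose in 19 and fell in 2 of 25 (20 and 2 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), among them the protease gene Ctsd (0.63 ± 0.08). Complement and acute phase genes rose in 9 of 13 (9 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation), with C3 at 1.15 ± 0.12. MHC class II genes rose in 7 of 8 (7 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation), with Cd74 at 0.21 ± 0.03.

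Cell cycle genes rose in 19 and fell in 3 of 33 in HCR (19 and 3 adjusted over the list alone; adjusted p = 0.464 with an estimated correlation), with Plk1 at 0.43 ± 0.07. Mucous cell markers rose in 9 and fell in 1 of 13 (10 and 1 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), among them Muc5b (1.30), Agr2 (1.44) and Gp2 (2.17). The mucous list mean was highest on HCR smoke 0415 (1.37), 0410 (1.12) and 0417 (1.002), 3 of the arrays with high heart muscle means, and on 0409 (-0.50) and 0416 (-0.42) it lay within the sham range of -0.70 to -0.04. The call ended with the interquartile range as a covariate (adjusted p = 0.197) and held at 0.0179 without HCR smoke 0410, 0414, 0415 and 0417. Alveolar type 1 markers fell in 10 of 11 genes (10 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation), including Ager (-0.39 ± 0.05) and Akap5 (-1.09 ± 0.19). Endothelial markers fell in 12 of 19 (12 adjusted over the list alone; adjusted p = 0.385 with an estimated correlation), including Ace (-0.49 ± 0.06) and Tie1 (-0.48 ± 0.07). Chaperone genes of the heat shock list rose in 5 of 13 (5 adjusted over the list alone; adjusted p = 0.745 with an estimated correlation), with Dnaja1 at 0.59, whose call ended with the interquartile range as a covariate (adjusted p = 0.0678). Of 23 immediate early genes, 8 rose (8 adjusted over the list alone; adjusted p = 0.844 with an estimated correlation), with Nr4a3 at 0.92. The heat shock call ended with median-centred arrays (adjusted p = 0.0612), array weights (0.0899), the Gapdh (0.102), Actb (0.0673) or interquartile range (0.401) covariate, without HCR sham 0432 (0.057) or HCR smoke 0415 (0.0513), without HCR smoke 0410, 0414, 0415 and 0417 together (0.124) and with fry (0.0579). The immediate early call ended with median-centred arrays (adjusted p = 0.169), quantile normalization (0.0971), the mean of probe sets (0.0814), a pseudocount of 1 (0.05), 2 groups in the fit (0.0555), an intensity trend (0.0519), without HCR sham 0433 (0.0992), LCR sham 0442 (0.0505) or HCR smoke 0417 (0.0786), and with fry (0.145). Scgb1a1 and Sftpc, the main club cell and type 2 cell products, did not pass (0.02 ± 0.03 and 0.01 ± 0.02). Their mean intensities on HCR sham arrays were 10450 and 10400, near the highest intensity in the table, 11560, where a rise can be understated. In LCR both genes passed, with 11 of 12 smoke arrays for Scgb1a1 and 12 of 12 for Sftpc on the same side of the sham mean. The Scgb1a1 call ended with 4 of the 38 arrays left out in turn, with median-centred arrays and with the Actb covariate. That of Sftpc ended with quantile normalization.

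In LCR animals, Cyp1a1 rose by 7.13 ± 0.14 log2 (SE, adjusted p = 3.2e-31), from an intensity of 18.1 ± 17.7 (SD, n = 7) to 4364 ± 343 (SD, n = 12). Lpo rose by 4.10 ± 0.40, Aldh3a1 by 3.66 ± 0.24, Orm1, an acute phase protein, by 3.47 ± 0.37, Slc26a4, the anion exchanger pendrin, by 3.44 ± 0.25 and Cyp1b1 by 3.39 ± 0.25. Lcn2, which binds bacterial siderophores, rose by 3.17 ± 0.43, with 1 sham array, LCR sham 0440, at 9.11 log2 where the others lay between 5.05 and 5.97. Mmp12 (2.99 ± 0.39), S100a9 (2.84 ± 0.28) and Cxcl6 (2.83 ± 0.31) followed. All of these were above the sham mean on 12 of 12 smoke arrays. The 10 largest falls were Bank1 (-1.82 ± 0.15), Dlk1 (-1.79 ± 0.29), the retinoic acid hydroxylase Cyp26b1 (-1.78 ± 0.18), and the airway P450 genes Cyp2a3 (-1.63 ± 0.62) and Cyp2f4 (-1.62 ± 0.47), followed by Spon2 (-1.51), Pcp4l1 (-1.49), Slc6a15 (-1.40), Prune2 (-1.31) and the clock gene Npas2 (-1.26). The call of Cyp2a3 ended without LCR sham 0440 (adjusted p = 0.065), 0441 (0.052) or 0442 (0.0973) and without LCR smoke 0426 (0.0535) or 0429 (0.0518), and with the Gapdh (0.0505) or Actb (0.0927) covariate.

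Between smoke and sham arrays in LCR, 7193 of 14217 genes differed, 3225 higher and 3968 lower after smoke. The median size was 0.26 log2 among the genes called. Changes of at least 1.5-fold were called for 742 genes (407 higher, 335 lower) and at least 2-fold for 158 (130 higher, 28 lower). Higher calls made up 44.8%, between 38.7% with the lowest genes left out and 64.8% with median-centred arrays. Here too, smoke arrays had lower medians, and most calls were higher once arrays were centred.

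In LCR, 7 of 8 aryl hydrocarbon receptor targets rose (7 adjusted over the list alone), with a median of 2.05 (adjusted p = 1.5e-08; adjusted p = 0.00225 with an estimated correlation). Of 35 NRF2 and glutathione genes, 26 rose and 2 fell (26 and 2 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), with Nqo1 at 1.98 ± 0.12, Hmox1 at 2.05 ± 0.28 and Gclc at 1.11 ± 0.17. Macrophage markers rose in 16 and fell in 2 of 20 genes (16 and 2 adjusted over the list alone), with a median of 1.18, among them Cd68 (1.80 ± 0.16) and Gpnmb (1.57 ± 0.13). Lysosomal genes rose in 22 of 25 and fell in none (22 adjusted over the list alone), including Ctsd (0.94 ± 0.08) and Ctss (0.84 ± 0.08). Cytokine and chemokine genes rose in 22 and fell in 3 of 30 (22 and 4 adjusted over the list alone), including Cxcl1 (2.12 ± 0.16) and Tnf (1.58 ± 0.15), while Il33 was among those that fell (-0.68). MHC class II rose in 7 of 8 genes (7 adjusted over the list alone), and complement and acute phase genes in 9 of 13 (9 adjusted over the list alone). The calls of these 5 lists were each lost at adjusted p = 0.129 with an estimated correlation.

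Neutrophil markers rose in 6 of 10 genes in LCR (7 adjusted over the list alone; adjusted p = 0.363 with an estimated correlation), with Il1r2 at 2.52 ± 0.26. Cell cycle genes rose in 22 and fell in 2 of 33 (23 and 2 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation), with Cdk1 at 0.86 ± 0.10 and Ube2c at 0.82 ± 0.11. Alveolar type 2 markers rose in 10 of 13 (10 higher and 1 lower adjusted over the list alone; adjusted p = 0.333 with an estimated correlation), including the surfactant genes Sftpd (0.43 ± 0.05) and Sftpa1 (0.24 ± 0.04). Lipid efflux and storage genes rose in 9 and fell in 3 of 16 (9 and 3 adjusted over the list alone; adjusted p = 0.363 with an estimated correlation), with Fabp5 (1.21 ± 0.09) and the cholesterol ester synthase Soat1 (0.94 ± 0.10) among them. Glycolysis and hypoxia genes rose in 11 and fell in 2 of 26 (11 and 2 adjusted over the list alone; adjusted p = 0.567 with an estimated correlation), with the lactate exporter Slc16a3 at 1.11 ± 0.14. The set test call ended with median-centred arrays (adjusted p = 0.0594).

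Smooth muscle and pericyte markers fell in 12 of 16 genes in LCR (14 adjusted over the list alone; adjusted p = 0.497 with an estimated correlation), including Pdgfrb (-0.86 ± 0.07) and Mylk (-0.50 ± 0.07). The smooth muscle list mean of LCR sham 0442 was high (1.26, against 0.04 to 0.49 on the other LCR sham arrays). Without this array the set test call held (adjusted p = 0.00199). Endothelial markers fell in 12 and rose in 1 of 19 (12 and 1 adjusted over the list alone; adjusted p = 0.333 with an estimated correlation), including Ace (-0.58 ± 0.06) and Tek (-0.57 ± 0.07). Alveolar type 1 markers fell in 9 and rose in 1 of 11 (9 and 1 adjusted over the list alone; adjusted p = 0.583 with an estimated correlation), with Cav1 at -0.25 ± 0.04. B and plasma cell markers fell in 9 and rose in 1 of 13 (9 and 1 adjusted over the list alone; adjusted p = 0.676 with an estimated correlation), including Fcmr (-0.86 ± 0.17) and Cr2 (-0.85 ± 0.21). This call ended without LCR sham 0442 (adjusted p = 0.079), with the lowest genes left out (0.296), with array weights (0.0584) and with the Actb covariate (0.066). The alveolar type 1 call ended with the lowest genes left out (adjusted p = 0.0526).

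The smoke changes of both lines ran together across genes, with Pearson r = 0.785 and Spearman rho = 0.741 over 14217 genes, which are not independent replicates. In 1 of 100 label permutations within lines, the real labels included, was r as large (permutation p = 0.01, the smallest these draws can give), and the highest permuted r was 0.565. Both lines called 1754 genes higher and 2941 lower, where independent lists of these lengths share 570.1 and 1205, and 37 genes were called in opposite directions.

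**Figure D2:**
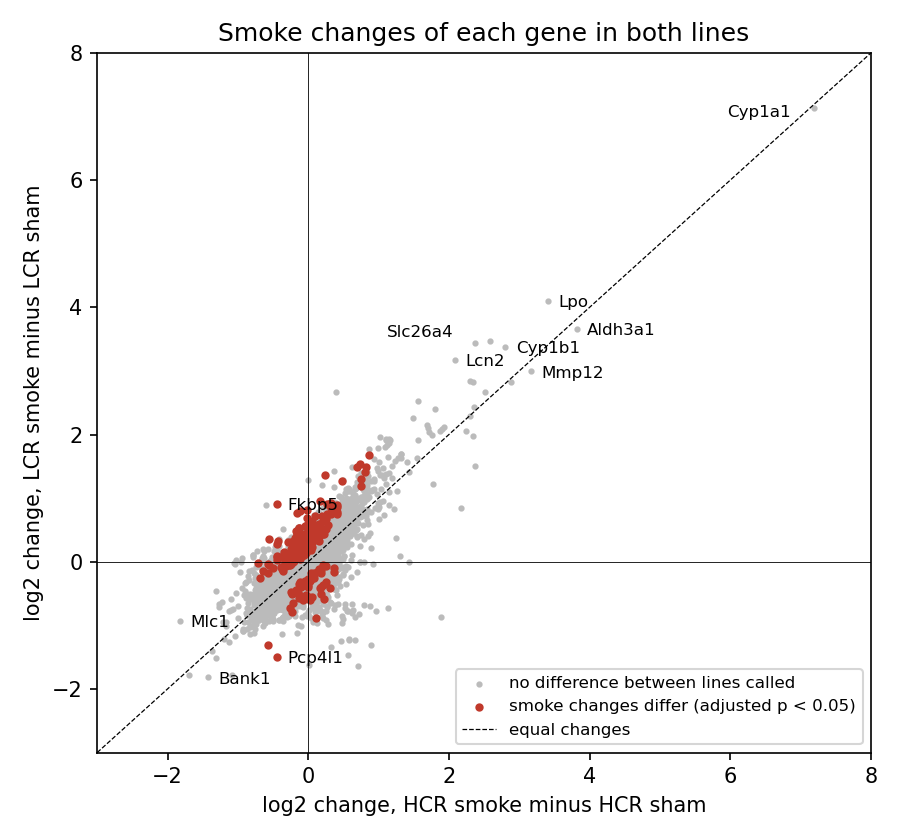
Each point is a gene, placed by its log2 change with smoke in HCR (x axis) and LCR (y axis), and red points are the 266 genes whose changes differed between the lines. Cyp1a1 lies near the dashed line of equal changes at 7.19 and 7.13.

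Between the lines under sham, genes of cytotoxic lymphocytes were higher in LCR. Prf1, which encodes the pore-forming perforin, was higher by 2.00 ± 0.37 log2 (SE, adjusted p = 0.0014), at an intensity of 613 ± 144 against 189 ± 172 (SD, n = 7 each). The granzyme genes Gzmk (1.39 ± 0.28), Gzmb (1.36 ± 0.31) and Gzmm (1.29 ± 0.20), the granule gene Nkg7 (1.32 ± 0.22) and the chemokine gene Ccl5 (1.56 ± 0.31) were also higher. Each of these 6 genes was above the HCR mean on 7 of 7 LCR arrays. Clec3b (1.80), Ifitm10 (1.41), Scrn1 (1.32) and Serpina1 (1.22) made up the rest of the 10 largest differences upward. Lowest in LCR were Mis18a (-1.99 ± 0.21), a gene of centromere assembly, Crxos1 (-1.42), Ooep (-1.33), the water and glycerol channel Aqp3 (-1.23), Cwc25 (-1.13), the glucocorticoid-induced Fkbp5 (-1.02 ± 0.26), Acot1 (-0.99), the cholesterol exporter Abca1 (-0.98), Moxd1 (-0.96) and Nupr1 (-0.86).

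Under sham, 531 of 14217 genes differed between the lines, 198 higher and 333 lower in LCR. Differences of at least 1.5-fold were called for 88 genes (47 higher, 41 lower). Higher calls made up 37.3%, with 20.6% for median-centred arrays, 48.7% with the Gapdh covariate and 50.9% with all probe sets. The count was 233 with only the sham arrays in the fit, 314 without HCR sham 0434 and 830 without HCR sham 0432. Of 52 genes the naming rule took, 32 kept their call whichever array was left out, and among the genes given here the calls of Crxos1, Abca1, Cspg4, Sftpd, Chi3l1, Ifi27, Acot1, Fkbp5 and Pdk4 ended with 21, 10, 9, 8, 7, 4, 3, 2 and 2 of the 38 arrays left out in turn. With only the sham arrays in the fit the calls of Crxos1, Abca1, Cspg4, Sftpd, Chi3l1, Acot1, Pdk4, Clec3b, Cd8a, Blk, Sult1a1 and Nupr1 ended. That of Crxos1 also ended with an intensity trend and robust variance, that of Abca1 with the mean of probe sets, and that of Cspg4 with the Gapdh covariate.

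Natural killer and cytotoxic markers were higher in LCR sham in 9 of 13 genes (11 adjusted over the list alone), with a median of 0.94 (adjusted p = 3.7e-18; adjusted p = 0.0302 with an estimated correlation). T cell markers were higher in 4 of 18 genes (7 adjusted over the list alone), including Cd247 (0.67 ± 0.12) and Cd8a (0.78 ± 0.19), and B and plasma cell markers in 1 of 13, Blk (0.50 ± 0.11; 1 adjusted over the list alone). These lists were called at adjusted p = 3.7e-05 and 7.1e-05, and both had adjusted p = 0.474 with an estimated correlation. Interferon response genes were higher in 2 of 28, Ifit1 (1.06) and Ifi27 (0.37), with 2 adjusted over the list alone, and adjusted p = 0.733 with an estimated correlation. Ciliated cell markers had a median of 0.34 and MHC class I genes of 0.07, and smooth muscle markers of 0.28. No member of these lists passed higher (0 adjusted over the list alone), and the smooth muscle gene Cspg4 was lower (-0.29; 1 adjusted over the list alone). With an estimated correlation the adjusted p was 0.733, 0.733 and 0.756. The smooth muscle call ended without LCR sham 0442 (adjusted p = 0.293) or HCR sham 0433 (0.0591), with array weights (0.102) and with the Gapdh covariate (0.0667). The MHC class I call ended without HCR sham 0432 (adjusted p = 0.169), with the lowest genes left out (0.0698) and with the Gapdh (0.102) or Actb (0.0724) covariate.

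Glucocorticoid response genes were lower in LCR sham in 5 of 14 (6 adjusted over the list alone; adjusted p = 0.246 with an estimated correlation), including Pdk4 (-0.86 ± 0.22), Sult1a1 (-0.52 ± 0.12) and Klf9 (-0.34). Klf9 falls outside the naming rule for this comparison, and its call was not followed across settings. Macrophage markers were lower in 4 of 20 genes (8 adjusted over the list alone), including Pparg (-0.46 ± 0.10) and Chi3l1 (-0.81 ± 0.22), and alveolar type 2 markers in 1 of 13, Sftpd (-0.21 ± 0.06; 8 adjusted over the list alone), each with adjusted p = 0.474 with an estimated correlation. Lysosomal genes were lower in 4 of 25 (5 adjusted over the list alone; adjusted p = 0.733 with an estimated correlation). Fatty acid oxidation genes were lower in 3 of 29 (5 adjusted over the list alone; adjusted p = 0.731 with an estimated correlation) and lipid efflux and storage genes in 1 of 16, Abca1 (4 adjusted over the list alone; adjusted p = 0.482 with an estimated correlation). Skeletal muscle markers had a median of -0.58 and fat cell markers of -0.50 with no member passing (0 adjusted over the list alone), both at adjusted p = 0.733 with an estimated correlation. Without HCR sham 0433, the array with high muscle and fat means, their set tests gave adjusted p = 0.635 and 0.301 (0.0534 and 0.0702 with only the sham arrays in the fit), and the fatty acid oxidation list 0.0675 and the lipid efflux list 0.0529. With fry the calls of the T cell (adjusted p = 0.11), B cell (0.11), interferon (0.424), ciliated (0.424), MHC class I (0.446), smooth muscle (0.505), lysosomal (0.189), fatty acid oxidation (0.107), skeletal muscle (0.203) and fat cell (0.189) lists ended.

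**Figure D3:**
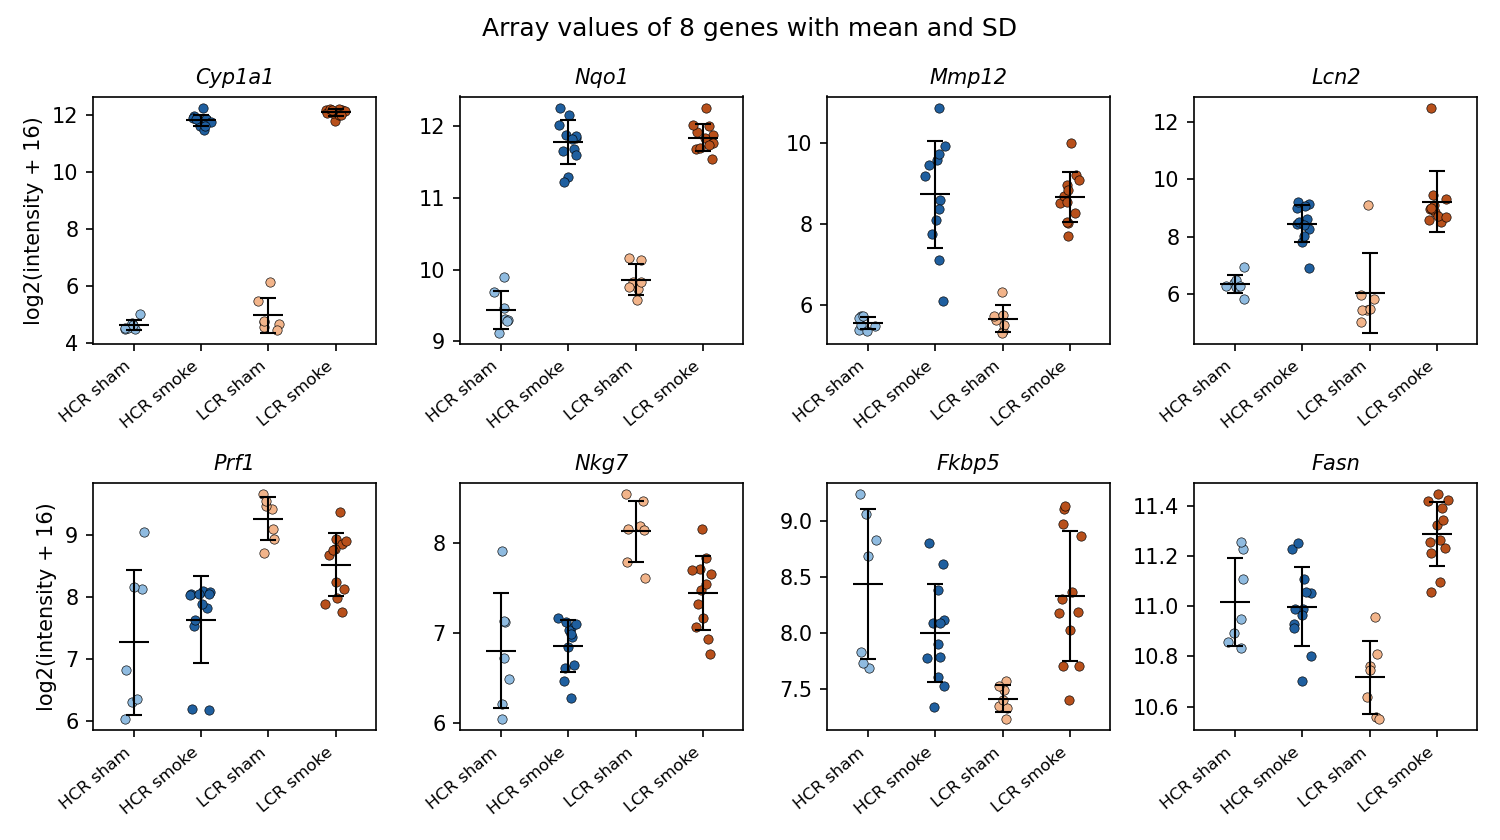
Each panel shows log2(intensity + 16) of a gene on all 38 arrays by group, with the group mean and SD as bars. Cyp1a1 shows no overlap of sham and smoke arrays in either line, and Prf1 spreads widely among HCR sham arrays, at an intensity of 189 ± 172.

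Between the lines under smoke, the MHC class II gene RT1-Ba had the largest difference, 3.28 ± 0.66 log2 higher in LCR (SE, adjusted p = 0.0025). Its intensity was 3249 ± 1373 in LCR smoke and 577 ± 987 in HCR smoke (SD, n = 12 each), and it lay above the HCR mean on 11 of 12 LCR arrays. The arrays took either low or high values within a group, with 10 HCR smoke arrays between 120.3 and 180.0 and HCR smoke 0410 and 0409 at 2683 and 2695, and with LCR smoke 0428 at 110.3 and the other LCR smoke arrays between 2585 and 5287. Of the other 3 probe sets of RT1-Ba, 1 differed alike (3.32 ± 0.70, unadjusted p = 3.3e-05), 1 was lower in LCR (-0.59 ± 0.14, unadjusted p = 0.000101) and 1 did not pass (-0.67 ± 0.37, unadjusted p = 0.081). A sequence variant under the probe set was not told apart from a change in RNA level. Cxcl14 (1.58 ± 0.19), Anks4b (1.38 ± 0.14), Clec3b (1.11 ± 0.26), the prostaglandin E synthase Ptges (0.96 ± 0.20), Crym (0.95 ± 0.10), the lipoxygenase Alox15 (0.91), Spp1 (0.86), Cemip2 (0.85) and Ccl5 (0.84) followed. Lower in LCR were Mis18a (-1.81 ± 0.16), the matricellular gene Ccn1 (-1.50 ± 0.43), the MHC class I gene RT1-A (-1.23 ± 0.29), Serpinf1 (-1.13 ± 0.28), Sfrp2 (-1.04), Ubd (-0.98), Omd (-0.86), Cwc25 (-0.85), Lypd2 (-0.79) and Trim16 (-0.77). RT1 genes are a family of close copies, so a probe set can bind several of them.

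Under smoke, 898 of 14217 genes differed between the lines, 656 higher and 242 lower in LCR, and 42 differed by at least 1.5-fold (25 higher, 17 lower). Higher calls made up 73.0%, with 54.7% for the interquartile range as a covariate, 56.1% after quantile normalization and 76.2% with the mean of probe sets. With the interquartile range as a covariate 364 genes were called, and with array weights 2860.

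Genes of cholesterol and fatty acid synthesis were higher in LCR smoke in 11 of 23 (18 adjusted over the list alone), including Cyp51 (0.45 ± 0.08), Nsdhl (0.27 ± 0.04) and Stard4 (0.29 ± 0.05). The list was called at adjusted p = 1.9e-10, with adjusted p = 0.22 with an estimated correlation. The lists that follow had an adjusted p of 0.855, 0.916 or 0.935 with an estimated correlation, as given. At 0.855, natural killer and cytotoxic markers were higher in 4 of 13 (9 adjusted over the list alone), including Ncr1 (0.44 ± 0.10). Lysosomal genes were higher in 3 of 25 (8 adjusted over the list alone), including Ctsk (0.55 ± 0.17), and cell cycle genes in 2 of 33 (5 adjusted over the list alone), Mcm6 (0.22) and Mad2l1 (0.22). T cell markers were lower in 1 of 18, Cd5 (-0.31; 5 adjusted over the list alone), and immediate early genes in 1 of 23, Ccn1 (3 adjusted over the list alone), also at 0.855. Heart muscle markers (median -0.93), smooth muscle markers (-0.41) and club cell markers (-0.31) had no member passing, with 0, 6 and 0 lower adjusted over the list alone, at 0.855 too. HCR smoke 0415 and 0410 had high means of all 3 lists, at 3.08 and 2.51 for heart muscle, 1.07 and 0.82 for smooth muscle and 1.20 and 1.15 for club cells, with 0417 at 1.17, 0.46 and 1.01. Without these arrays and 0414 the heart muscle and club cell calls ended (adjusted p = 0.457 and 0.189), and the smooth muscle call held at 0.0199. Alveolar type 1 markers were higher in 2 of 11 (5 adjusted over the list alone) and B cell markers had a median of -0.22 with none passing (0 adjusted over the list alone), both at 0.916. Interferon response genes were lower in 2 of 28, Ifi44 (-0.32) and Herc6 (-0.35), at 0.935 (1 higher and 2 lower adjusted over the list alone). Of 59 genes the naming rule took, 42 kept their call whichever array was left out, and among the genes given here the calls of Ifi44, Cd5, Spp1, Ctsk, Sfrp2, Ccl5 and Ccn1 ended with 26, 21, 14, 12, 12, 4 and 4 of the 38 arrays left out in turn. With only the smoke arrays in the fit the calls of Spp1, Ctsk, Sfrp2, Ifi44 and Mad2l1 ended, and with the interquartile range these 5 and those of Clec3b, Alox15, Herc6, Ubd, Serpinf1, RT1-A and Ccn1. Quantile normalization also ended the calls of Spp1 and Ctsk, a pseudocount of 1 that of Spp1, and median-centred arrays that of Ifi44. The alveolar type 1 call ended with the lowest genes left out (adjusted p = 0.14), array weights (0.108) and the Gapdh (0.0572) or Actb (0.0542) covariate, and without HCR smoke 0410 (0.0912) or 0415 (0.101) or without HCR smoke 0410, 0414, 0415 and 0417 together (0.209). The B cell call ended without these 4 arrays (0.0636), and the T cell call with the lowest genes left out (0.051). With fry the calls of the natural killer (adjusted p = 0.0662), lysosomal (0.0687), cell cycle (0.0687), T cell (0.262), immediate early (0.262), heart muscle (0.174), smooth muscle (0.088), club cell (0.115), alveolar type 1 (0.174), B cell (0.301) and interferon (0.491) lists ended.

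The line differences under sham and under smoke were weakly related across the 14217 genes, with Pearson r = 0.152 and Spearman rho = 0.058. Of 100 label permutations within exposures, 26 gave an r as large (permutation p = 0.26). Both exposures called 57 genes higher and 38 lower in LCR, where independent lists share 9.14 and 5.67, and 10 genes had opposite directions. Mis18a, Cwc25, Clec3b and Ccl5 were among the 10 largest differences of their direction under both exposures.

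The response to smoke differed between the lines for 266 of 14217 genes, 216 with a more positive and 50 with a more negative change in LCR. Fkbp5, a glucocorticoid-induced chaperone gene, had the largest positive difference, 1.35 ± 0.33 log2 (SE, adjusted p = 0.029), with a rise of 0.91 ± 0.23 in LCR and a change of -0.44 that did not pass in HCR. Fasn, the fatty acid synthase, rose by 0.57 ± 0.07 in LCR and not in HCR (-0.02), a difference of 0.59 ± 0.10 (adjusted p = 0.0022). The T cell receptor genes Cd3g (-0.69 ± 0.19) and Cd247 (-0.62 ± 0.16), the kinase gene Lck (-0.58 ± 0.15) and the transcription factor gene Bcl11b (-0.58 ± 0.14) changed more negatively in LCR. Under sham, Fkbp5 and Fasn were called lower and Cd247 and Lck higher in LCR than in HCR. Such a sham difference enters these values with the opposite sign. The rest of the 10 largest positive differences were Mro (1.12 ± 0.21), Krt79 (0.93), Kcnmb4 (0.92), Chodl (0.91), Slc7a7 (0.83), Plet1 (0.82), Slc47a1 (0.81), Mab21l3 (0.80 ± 0.14) and Fetub (0.79). Together with Cd3g, Cd247, Lck and Bcl11b, the 10 largest negative ones were Pcp4l1 (-1.05 ± 0.27), Mnda (-0.998), Pik3c2b (-0.81 ± 0.13), Prune2 (-0.74), the chemokine gene Cxcl12 (-0.73) and Shc2 (-0.63).

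Of the 266 genes, 135 were called for smoke in LCR alone, 48 in HCR alone, 51 in both lines with the same direction and 32 in both with opposite directions. Differences of at least 1.5-fold were called for 39 genes. The count was 768 without HCR sham 0432, the array with the highest Actb and Gapdh 3' minus 5' differences. For other HCR sham arrays it was 81 without 0434, 129 without 0435, 107 without 0436 and 518 without 0439. For LCR sham arrays it was 114 without 0441, 152 without 0442 and 103 without 0445, and for smoke arrays 404 without HCR 0412, 175 without HCR 0419, 417 without LCR 0420 and 170 without LCR 0429. Of the 33 genes the naming rule took, 13 kept their call whichever array was left out, and the calls of the other 20 ended with some of the 38 arrays left out in turn. These were Pfkp and Slc47a1 (25 arrays each), Slc7a7 (24), Cd3g and Pparg (22 each), Krt79 (21), Lck (20), Cxcl12 (18), Mrc1 (13), Pcp4l1 (10), Chodl (9), Npc2 (6), Cd247, Mnda and Shc2 (5 each), Eomes and Fkbp5 (4 each), Bcl11b and Kcnmb4 (3 each) and Gla (2). With the interquartile range the calls of Krt79, Slc7a7, Slc47a1, Mrc1, Pparg, Pfkp and Lck ended, with the mean of probe sets those of Pfkp, Eomes, Bcl11b, Shc2, Cxcl12 and Mnda, and with a pseudocount of 1 that of Pfkp.

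Among gene groups, 17 lists differed between the responses by the set test with a preset correlation and none with an estimated correlation. The sham arrays of both lines are part of this comparison, so a line difference under sham enters it with the opposite sign. More positive in LCR were lysosomal genes, with 4 of 25 passing (16 adjusted over the list alone) including Ctsh (0.40 ± 0.08) and Npc2 (0.29 ± 0.07). So were cholesterol and fatty acid synthesis genes, with 5 of 23 (8 adjusted over the list alone) including Elovl1 (0.30) and Nsdhl (0.32). Macrophage markers followed, with 2 of 20, Mrc1 (0.62) and Pparg (0.48; 9 adjusted over the list alone). Glucocorticoid response genes passed in 1 of 14, Fkbp5 (2 adjusted over the list alone), and alveolar type 2 and lipid efflux genes in none (9 and 5 adjusted over the list alone). More negative were T cell markers, with 3 of 18 passing (8 adjusted over the list alone), and natural killer markers with 1 of 13, Eomes (-0.51; 7 adjusted over the list alone). So were B cell, club cell and smooth muscle markers with none (3, 2 and 9 lower adjusted over the list alone, with 1 smooth muscle gene higher). All of these had adjusted p = 0.247 with an estimated correlation. Fatty acid oxidation genes passed in 1 of 29, Ucp2 (0.42; 5 adjusted over the list alone), with adjusted p = 0.422 with an estimated correlation. No member passed among interferon (adjusted p = 0.388 with an estimated correlation), ciliated (0.57), cell cycle, heat shock and heart muscle genes (0.672 each), with 1 cell cycle gene and 0 of the others adjusted over the list alone. LCR sham 0442 had list means of 3.31 for heart muscle, 1.26 for smooth muscle and 1.25 for club cells, and HCR smoke 0410 and 0415 were high for the same lists. Without LCR sham 0442 the heart muscle list had adjusted p = 0.0143 and the club cell list 0.00311. Without HCR smoke 0410, 0414, 0415 and 0417 the heart muscle call ended (adjusted p = 0.289) and the club cell, smooth muscle and B cell calls held at 0.0108, 7.5e-05 and 2.2e-06. The cell cycle call ended with the lowest genes left out (adjusted p = 0.28) and without HCR sham 0432 (0.0517). The heat shock call ended with array weights (adjusted p = 0.202), the Gapdh (0.124), Actb (0.0903) or interquartile range (0.214) covariate, and without HCR sham 0432 (0.177), LCR sham 0442 (0.144), HCR smoke 0414 (0.0929), HCR smoke 0415 (0.0976) or HCR smoke 0410, 0414, 0415 and 0417 together (0.29). With fry the calls of the natural killer (adjusted p = 0.0671), club cell (0.11), smooth muscle (0.0709), interferon (0.176), ciliated (0.3), cell cycle (0.176), heat shock (0.465) and heart muscle (0.373) lists ended.

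**Figure D4:**
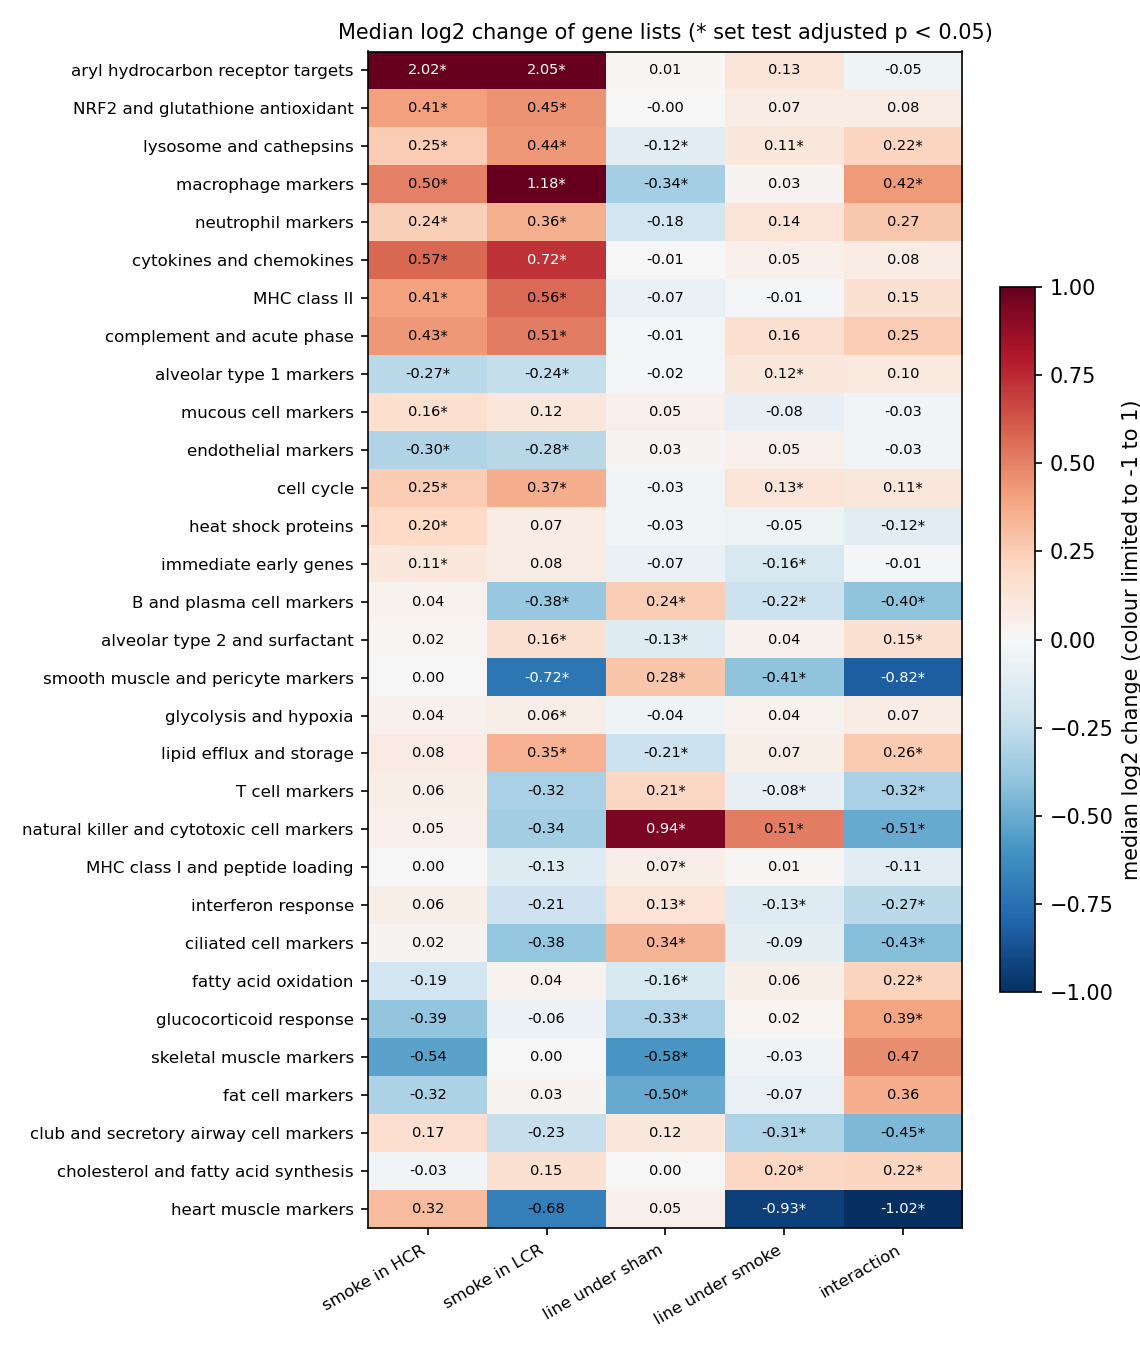
Cells give the median log2 change of the members of each of 31 gene lists (rows) in the 5 comparisons (columns), with colour from blue (negative) to red (positive) and an asterisk where the set test with a preset correlation had an adjusted p under 0.05. Macrophage markers had a median of 0.50 in HCR and 1.18 in LCR after smoke, and natural killer markers 0.94 between the lines under sham.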

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

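The tests on Actb, lymphoid tissue and blood were chosen only after the result was seen. Sham arrays were examined for values far from the rest of their group, and smoke groups, with 12 arrays each, were not examined in this way. Chance alone marks about 1 in 20 groups. Among 277 named genes an array stood apart in 18 (6.5%) in HCR sham and 26 (9.39%) in LCR sham.

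HCR sham 0432 had 3' minus 5' differences of 1.218 for Gapdh (others 0.03 to 0.30) and 2.072 for Actb (others 0.63 to 0.83), and stood apart in 6 named genes (0 to 4 for the others). HCR sham 0433 had list means of 3.77 for skeletal muscle, 2.37 for fat cells and 0.37 for the tricarboxylic acid cycle, and a Cyp1a1 value of 5.02 log2 (others 4.47 to 4.68). HCR sham 0439 had a complement list mean of -0.75 (others -0.47 to -0.31). LCR sham 0440 had an Lcn2 value of 9.11 (others 5.05 to 5.97) and a red blood cell list mean of 0.25 (others -0.31 to -0.15).

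LCR sham 0442 had a mean correlation of 0.985 with its group (others 0.992 to 0.993) and stood apart in 18 named genes (0 to 3 for the others). Its list means were 3.31 for heart muscle, 1.26 for smooth muscle, 1.25 for club cells, 0.76 for mucous cells and -0.050 for alveolar type 1 cells. They were 0.32 for oxidative phosphorylation, 0.22 for fatty acid oxidation, 0.29 for the tricarboxylic acid cycle, 0.10 for glycolysis and 0.16 for skeletal muscle. Its Mmp12 was 6.34 log2 (others 5.33 to 5.75) and its Gclc 7.65 (others 7.24 to 7.41).

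The change with smoke in LCR minus that in HCR passed for 33 named genes. It was 1.35 for Fkbp5, 1.12 for Mro, 0.93 for Krt79, 0.92 for Kcnmb4, 0.91 for Chodl, 0.83 for Slc7a7, 0.82 for Plet1, 0.81 for Slc47a1, 0.80 for Mab21l3, 0.79 for Fetub, 0.62 for Mrc1, 0.59 for Fasn, 0.48 for Pparg, 0.46 for Edem1, 0.42 for Ucp2, 0.40 for Ctsh, 0.33 for Gla, 0.32 for Pfkp, 0.32 for Nsdhl, 0.30 for Elovl1, 0.29 for Npc2 and 0.25 for Pigr. It was -0.51 for Eomes, -0.58 for Lck, -0.58 for Bcl11b, -0.62 for Cd247, -0.63 for Shc2, -0.69 for Cd3g, -0.73 for Cxcl12, -0.74 for Prune2, -0.81 for Pik3c2b, -0.998 for Mnda and -1.05 for Pcp4l1. List medians were 0.42 for macrophage markers, 0.39 for glucocorticoid response, 0.26 for lipid efflux, 0.22 for lysosome, 0.22 for fatty acid oxidation, 0.22 for cholesterol and fatty acid synthesis, 0.15 for alveolar type 2 and 0.11 for cell cycle genes. They were -0.12 for heat shock, -0.27 for interferon, -0.32 for T cell, -0.40 for B cell, -0.43 for ciliated, -0.45 for club, -0.51 for natural killer, -0.82 for smooth muscle and -1.02 for heart muscle genes.

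The first pattern is the opposite shift of lymphocyte lists and of macrophage, lysosome and lipid lists in the interaction. The interaction is also the line difference under smoke minus that under sham, so it reuses the sham arrays. Of the 11 lists followed, all but cholesterol and fatty acid synthesis were also called between the lines under sham, in the opposite direction. The pattern therefore restates the sham difference in part. Each array's mean of ciliated, club, smooth muscle and heart muscle markers was used as a covariate. The median ratio of the list shifts to those without it was 0.927 (0.663 to 1.57, above 0.5 in 11 of 11 lists). This argues against different pieces of lung as the whole cause only as far as this score follows them. Heart muscle markers varied most in the score, whose median correlation within groups with the genes called was -0.189. The score averaged -0.0134 on HCR sham, 0.178 on HCR smoke, 0.215 on LCR sham and -0.295 on LCR smoke arrays. The same covariate ended most gene calls, from 266 to 46, with 42 called both ways, while changes kept a median 0.897 of their size and standard errors 1.04, so pieces may still account for part of single genes. With the Actb difference as a covariate the ratio was 1.03 (0.982 to 1.1) and 629 genes were called. The Actb difference was 2.07 on HCR sham 0432 and at most 1.08 on any other array. That fit therefore adjusts mostly for a single array and cannot decide on RNA degradation. A difference between the lines in the response stays open and untested as a hypothesis, and no list of the interaction kept its call with an estimated correlation.

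The second pattern is the higher cytotoxic lymphocyte genes in LCR sham, by 0.923 log2 in the list mean (exact permutation p = 0.00175). Lymphoid tissue in the pieces would bring B cell genes as well, but the cytotoxic list exceeded the B cell list's own difference of 0.285 by 0.639 (exact permutation p = 0.0128), and the abundant plasma cell gene Jchain differed by 0.19 ± 0.16 (SE). Blood left in the lung would bring red cell and neutrophil genes, whose difference was -0.164, and the cytotoxic list exceeded it by 1.09 (exact permutation p = 0.00175), with the globin gene Hbb at -0.11 ± 0.07. More cytotoxic cells in lungs of the LCR line may account for it, and this was not tested.

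The third pattern is the 95 genes that differed between the lines in the same direction under both exposures. Sequence variants under a probe set could give such a difference without a change in RNA level. Of 22 other probe sets of 18 of these genes, 10 (45.5%, exact binomial interval 24.4 to 67.8) differed the same way with unadjusted p under 0.05 in both comparisons, against 52.4% (464 of 885) for genes called for smoke in both lines with changes of like size. Variants and expression cannot be told apart, because the interval reaches below 0.5 of the share in smoke genes as well as above that share.

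Other splits of the arrays were compared with the real groups, 100 per comparison with the real split included. As many genes were called in 1 split for smoke in HCR (6830, highest other 2353) and in 1 for smoke in LCR (7193, highest other 2747). Chance can be excluded there at this number of splits. The splits do not tell smoke from the order of the array numbers, which run in blocks by group. For the interaction, 1 split called as many as well, the real one (266, highest other 13). Its splits shuffled line labels within each exposure, which also removes the line differences shared by both exposures. They therefore cannot decide on chance for the interaction alone. For the lines under sham 2 splits called as many, the real one (531) and another with 743, and under smoke 2, the real one (898) and another with 1948. These shares lie under the threshold of 0.05 set beforehand. Another drawn split exceeded the real count in either comparison, and with 100 splits so small a share is itself uncertain. Chance is therefore not firmly excluded there. The correlation of the line differences between exposures did not pass its test either (permutation p = 0.26).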

How the results depend on the processing

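The interquartile range and Actb covariates, and list tests without HCR sham 0432 or 0433, LCR sham 0442 or HCR smoke 0410, 0414, 0415 or 0417, were chosen only after the result was seen. The cause of each change was not tested, except where all probe sets add features or a size minimum takes a subset. No signal over background was measured here, so for genes near the lowest intensities a change that was not called was not detectable rather than absent. Counts for smoke in HCR (6830) were 12324 with all probe sets, 3023 with the interquartile range and 453 with at least 1.5-fold change, and in LCR (7193) 13229 with all probe sets and 742 with the size minimum. Counts between the lines under sham (531) were 815 median-centred, 233 with only these groups in the fit, 1240 with all probe sets, 946 with array weights, 827 with the interquartile range and 88 with the size minimum. Under smoke (898) they were 2860, 364 and 42 with weights, interquartile range and size minimum. Interaction counts (266) were 549 median-centred, 531 with all probe sets, 1537 with weights, 565 with Gapdh, 629 with Actb and 39 with the size minimum. With 1 array left out, counts ranged from 6262 to 6985 for smoke in HCR, 6605 to 7367 in LCR, 314 (without HCR sham 0434) to 830 (without HCR sham 0432) under sham and 599 to 1246 under smoke. For the interaction they ranged from 81 (without HCR sham 0434) to 768 (without HCR sham 0432), with 129, 107 and 518 without HCR sham 0435, 0436 and 0439, 114, 152 and 103 without LCR sham 0441, 0442 and 0445, 404 and 175 without HCR smoke 0412 and 0419, and 417 and 170 without LCR smoke 0420 and 0429. The correlation of smoke changes stayed between 0.734 and 0.820 and that of line differences between 0.085 and 0.273. In HCR, Calb2 (-0.0928, adjusted p = 0.0857), Syp (-0.0219, 0.824), Nppb (-0.0286, 0.805) and Myl2 (-0.0266, 0.631) with the interquartile range, and Canx (0.01425, 0.877) with the mean of probe sets, lost their calls with values near 0 of the opposite sign. Of 74 list calls, 4 held with an estimated correlation and 43 with fry. Without HCR smoke 0410, 0414, 0415 and 0417 together 67 held and 7 ended. Of the named genes that passed, calls held in every setting and with each array left out for 90 of 128 in HCR, 116 of 128 in LCR, 21 of 52 under sham, 24 of 59 under smoke and 13 of 33 in the interaction. Groups share no replicate numbers, and no paired analysis was possible because the animals are separate.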

Other observations

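The list tests without LCR sham 0442 were chosen only after the result was seen, and Bmal1, Clock, Per1, Bhlhe40 and Eln were chosen after their values were seen. Clock genes moved in both directions with smoke in both lines. Npas2, a partner of Bmal1 in the clock, fell by 1.12 ± 0.22 (SE) in HCR and 1.26 ± 0.22 in LCR, Per1 by 0.72 and 0.78, and Clock by 0.26 and 0.24. Per2 rose by 0.95 ± 0.23 and 0.85 ± 0.23, Cry1 by 0.35 and 0.49, Bhlhe40 by 0.44 and 0.61, and Bhlhe41 by 0.82 and 1.04. Bmal1 fell by 0.72 in HCR and had a change of -0.47 that did not pass in LCR, and the difference did not pass either (interaction adjusted p = 0.73). Of 18 measured clock genes, 4 rose and 4 fell in each line (4 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.49 and 0.871). Of all 14217 genes, 2513 rose and 4317 fell in HCR, and 3225 rose and 3968 fell in LCR. These counts do not set the clock list apart.

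Some matrix and mast cell genes fell, as did 4317 of all 14217 genes in HCR and 3968 in LCR. The counts below do not set these lists apart. Of 29 collagen and extracellular matrix genes, 10 fell and 1 rose in HCR and 10 fell in LCR (the same counts adjusted over the list alone), among them elastin (Eln, by 0.86 ± 0.23 in HCR and 0.84 ± 0.23 in LCR). The list was not called in HCR (adjusted p = 0.397) or LCR (adjusted p = 0.0592, and 0.0197 with median-centred arrays). Of 14 mast cell and basophil genes, 4 fell in HCR and 2 in LCR (4 and 2 adjusted over the list alone), with no call of the list (adjusted p = 0.477 and 0.357). The mast cell receptor gene Kit fell by 0.52 ± 0.20 and 0.75 ± 0.20, and Gata2 by 0.60 ± 0.09 and 0.53 ± 0.09. Ppargc1a, a coactivator of mitochondrial genes, fell by 0.69 ± 0.09 and 0.73 ± 0.09.

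In LCR, 10 of 18 T cell markers fell with smoke and 1 rose (10 and 1 adjusted over the list alone), with Tcf7 at -0.76 ± 0.10 and Cd8a at -0.76 ± 0.17. Of 13 natural killer and cytotoxic markers, 5 fell (5 adjusted over the list alone), with Gzmm at -0.76 ± 0.18. These lists were not called (adjusted p = 0.0553 and 0.0939), and were with median-centred arrays (adjusted p = 0.0179 and 0.0354). The thymus markers measured were Satb1, which fell by 0.39 in HCR and 0.68 in LCR, and Cd1d1, which fell by 0.54 and 0.29.

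Oxidative phosphorylation genes had no member called between the lines under sham (0 of 46 passing, 0 adjusted over the list alone, median -0.03, adjusted p = 0.336), and without LCR sham 0442 the set test gave adjusted p = 4.0e-06. Tricarboxylic acid cycle genes were lower in LCR sham in 2 of 18 (3 adjusted over the list alone, adjusted p = 0.148), and without LCR sham 0442 their set test gave adjusted p = 0.000262. HCR sham 0433, the array with high skeletal muscle markers, stayed in both of these tests. Its means of the 2 lists, 0.26 and 0.37, were the highest of HCR sham. No test left out both arrays, so a line difference in these lists was not shown. With smoke, 7 of 24 protease and inhibitor genes rose and 4 fell in HCR, and 9 rose and 3 fell in LCR (the same counts adjusted over the list alone, adjusted p = 0.138 and 0.17). Of 26 unfolded protein response genes, 4 rose and 2 fell in HCR and 9 rose and 5 fell in LCR (the same counts adjusted over the list alone, adjusted p = 0.342 and 0.139). Lists of red blood cell, mesothelial and nerve markers were not called in any of the 5 comparisons.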
